A study of Mus musculus with 8 samples.

How the data were processed

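CD4+ T cells of 4 B6 and 4 Sle1a.1 female mice were profiled, per the labels, which call the arrays of a strain biological replicates. RNA was extracted with a column kit for small samples and turned into biotin-labelled amplified cDNA with the NuGEN Ovation system, per the labels' protocols. Linear amplification from the 3' end favours 3' probe sets, so the signal of 5' against 3' control probe sets was reported per array. The deposited table gives 1 value per probe set and array on a log10 scale; the authors' summarization, background correction and normalization are not given in the sources used here. The base was taken from the values: near the low end the number of values per unit grew by a factor of 8.09 to 11.1 across arrays, as for the log10 of a signal spread evenly near 0, and another base would rescale every printed difference. Between 16.2% and 19.8% of probe sets per array shared that array's lowest value, which was between -4.74 and -4.20, and such values have no order.

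Medians of the deposited log10 values were 0.53, 0.52, 0.54 and 0.52 for B6 replicates 1 to 4 and 0.54, 0.53, 0.69 and 0.55 for Sle1a.1 replicates 1 to 4. Quartiles differed by up to 0.80 on log2, above the limit of 0.1 set before the data were examined, so the values were turned to log2 and quantile normalized. A floor was then set at the 95th percentile of the values of 27 bacterial control probe sets (log10 0.135, log2 0.45), and lower values were raised to it. This floor was chosen after the distribution of values was seen and before any test, and the plan made beforehand had none. Where a strain was at the floor on any of its arrays, the fold or difference is a lower bound, since values were raised to the floor. The 64 control probe sets were left out, and 45037 were tested.

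Gene symbols came from the probe annotation, in which 34945 tested probe sets had 1 symbol, 932 had several and were not named, and 9160 were not listed and remain unnamed here. Updating through gene identifiers changed 0 symbols. Pbx1 and several T cell genes have no listed probe set and were not analysed. Gene order came from a table of the assembly GRCm38.p6, and no coordinates are given because the labels and the value table name no build of their own.

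Differences were fitted with limma 3.58.1 in R 4.3.3 (lmFit and eBayes, two-sided, Benjamini-Hochberg over all probe sets tested, threshold 0.05). In 5 simulations with the means and spreads of these arrays, changes were planted among 45037 probe sets, only in ones well above the floor. The noise was normal and independent between probe sets. Of log2 changes of 1, 39.4% were recovered, and of log2 changes of 2, 82.2%. These shares do not apply to changes near the floor. In the same simulations 9.25% of calls were false, above the nominal 5%, and 3.19% were false with trend and robust settings. Gene lists were tested with camera on the brightest probe set of each of 18193 genes, with a preset correlation of 0.01 and with an estimated one. The neighbours of Pbx1 were tested with Fisher's exact test. Figures were drawn with matplotlib 3.10.9.

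Named are the 12 genes with the largest rise and the 12 with the largest fall among probe sets past the threshold with 1 symbol (the smallest p per gene), up to 4 members with the smallest p of each list described, the sex-linked genes, and neighbours of Pbx1 past the threshold, of which there were 0. Globin genes, the second probe sets of named genes and the neighbours Cd247, Nuf2 and Uap1 were added after their values were seen. So were the genes of chromosome 9, the neighbours of Ighm, and Foxp3, Ikzf4, Entpd1, Bcl6, Cxcr5 and Icos. The rule, the lists, the tests and most alternatives were fixed before the data were examined. Alternatives covered normalization, dim probe sets, variance model, array weights, a block by replicate number, each array left out, the threshold, probe sets that may cross-hybridize, the probe set per gene and the width of the neighbourhood. Other floors or none, a constant added to the signal, leaving out probe sets at the floor on all arrays, leaving out B6 replicates 1 and 2 together and the Gapdh end ratio as a covariate were chosen after seeing the data.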

Results

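Gene expression was measured in CD4+ T cells, the helper and regulatory T cells of the immune system, from female mice of the strain C57BL/6 (B6) and of the congenic strain B6.Sle1a.1 (Sle1a.1). A congenic strain carries a chromosome segment of another strain on a common background, and the series title names the homeobox gene Pbx1 and susceptibility to lupus. The 8 arrays comprised 4 biological replicates per strain, and 1 array was hybridised per replicate. The sample descriptions name B1a cells and the design text once names B6.Sle2c1, and the titles of the congenic samples name Sle1a without the final number. The source names give CD4+ T cells of B6 and B6.Sle1a.1 mice and the genotypes give B6.Sle1a.1, and these were followed. Values below are normalized signals on a log2 scale, given as mean ± SD over the 4 arrays of a strain, and differences are Sle1a.1 minus B6. A floor at a log2 value of 0.45 was set for signals that could not be told from background, and 63.8% to 64.1% of probe sets lay above it on each array. The number of arrays limits the precision of every comparison.

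The arrays correlated between 0.924 and 0.984. The first principal component held 38.6% of the variance and placed B6 replicate 2 and Sle1a.1 replicate 3 at opposite ends. All B6 arrays lay below all Sle1a.1 arrays on it (highest B6 value -0.62 in replicate 3, lowest Sle1a.1 value 12.8 in replicate 1). Xist, the X-inactivation transcript of female cells, was bright on all 8 arrays, with means of 7.71 ± 0.24 in B6 and 8.02 ± 0.24 in Sle1a.1 for 1 of its 3 probe sets. The Y-linked gene Eif2s3y was at the floor on all 8 arrays, and Kdm5d and Uty had means of at most 0.79 ± 0.39. RNA ends differed between the arrays. The signal of the 5' end of Gapdh relative to its 3' end was -2.52 ± 1.49 in B6 and -1.23 ± 0.20 in Sle1a.1 (exact permutation test, two-sided p = 0.171). The same measure of Actb was -2.72 ± 1.20 in B6 and -1.68 ± 0.13 in Sle1a.1 (exact permutation test, two-sided p = 0.0286). B6 replicates 1 and 2 held the lowest values of both genes. For Actb, all 4 B6 arrays lay below all 4 Sle1a.1 arrays (highest B6 value -1.79, lowest Sle1a.1 value -1.76). The p of 0.0286 is the smallest that this permutation test can give with 70 relabelings. Leaving out B6 replicates 1 and 2 therefore does not remove the strain difference of Actb ends.

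**Figure D1:**
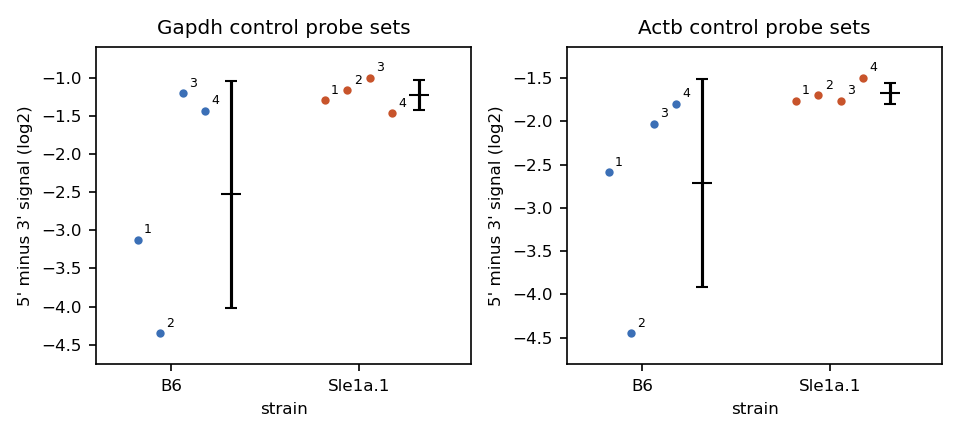
Signal of the 5' control probe set minus that of the 3' control probe set (log2, vertical axis) for Gapdh and Actb by strain (horizontal axis). Each point is 1 array with its replicate number, and the black mark with its bar is the mean ± SD of 4 arrays; B6 replicate 2 lies lowest in both panels, at -4.35 for Gapdh and -4.45 for Actb.

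The main comparison asked which transcripts differed between CD4+ T cells of both strains. Among named genes, the widest changes were seen for a probe set of Ighm, the constant region of the immunoglobulin mu heavy chain, and for Scn2b, a sodium channel beta subunit. The Ighm probe set was at the floor on all 4 B6 arrays and at 8.44 ± 1.55 in Sle1a.1, at least 255-fold higher (limma, adjusted p = 0.0308). Other Ighm probe sets were bright in both strains. The brightest of them were at 8.18 ± 0.11 and 7.17 ± 0.52 in B6, and at 8.29 ± 0.48 and 7.66 ± 0.31 in Sle1a.1. Scn2b fell from 6.76 ± 0.27 in B6 to 0.70 ± 0.17 in Sle1a.1, at least 66.4-fold lower, with 1 Sle1a.1 array at the floor (adjusted p = 1.1e-04); its other probe set above the floor had a difference of -0.23 (unadjusted p = 0.694). Erdr1 was 7.31-fold higher in Sle1a.1, at 10.04 ± 0.15 against 7.17 ± 0.46 (adjusted p = 0.0190). Nnt, the mitochondrial nicotinamide nucleotide transhydrogenase, was 2.16-fold lower, at 8.29 ± 0.10 against 9.41 ± 0.09 (adjusted p = 0.00340).

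Further genes were higher in Sle1a.1. Tmprss13, a transmembrane serine protease, was at the floor in B6 and at 3.64 ± 0.18 in Sle1a.1, at least 9.15-fold higher (adjusted p = 1.1e-04). Cbx3, a heterochromatin protein of the HP1 family, was at 5.44 ± 0.82 in Sle1a.1 and above the floor on 1 of 4 B6 arrays, at least 30.9-fold higher (adjusted p = 0.0190). Pml, the scaffold of PML nuclear bodies, rose from 3.17 ± 0.19 to 5.17 ± 0.31 (adjusted p = 0.0273), while a second and brighter probe set of Pml had a difference of -1.49 (unadjusted p = 0.00419, adjusted p = 0.312). Single probe sets of Zfp82 and Spsb4 were at the floor in B6 and at least 4.43-fold and 2.89-fold higher in Sle1a.1. A probe set of Dhx58, which encodes the RNA helicase LGP2 of the antiviral RIG-I-like receptor pathway, was at the floor in B6 and at least 2.43-fold higher in Sle1a.1, whereas a brighter one was at 3.74 ± 0.15 in B6 and 3.85 ± 0.34 in Sle1a.1 (unadjusted p = 0.532 in limma's fit). The changed probe sets of Mcm9, a helicase of DNA repair, Rps6ka3, which encodes the kinase RSK2, and Tmem178b were above the floor on 1 of 4 B6 arrays and Cnnm4 on 2, and all 4 arrays of Sle1a.1 were above it. They rose by at least 1.37, 1.30, 1.97 and 1.45.

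Among the genes with a probe set that fell in Sle1a.1, Sorl1, a sorting receptor of the VPS10 family, went from 6.14 ± 0.27 to 4.71 ± 0.16 (adjusted p = 0.0418). Its 2 other probe sets, the first of them brighter, had differences of 0.40 and 0.13 (unadjusted p = 0.124 and 0.591 in limma's fit). A fall of the gene as a whole was therefore not shown. Arel1, an E3 ubiquitin ligase, went from 4.56 ± 0.15 to 2.76 ± 0.36 (adjusted p = 0.0404). The proteasome assembly factor Psmg3 went from 5.51 ± 0.13 to 4.27 ± 0.23 (adjusted p = 0.0386), and Gm38983 from 4.43 ± 0.29 to 1.70 ± 0.28 (adjusted p = 0.0103). Vps18, a subunit of endosomal tethering complexes, Med12l, Tmem177 and St8sia5 had differences of -2.15, -1.77, -1.14 and -1.06 or lower, with Sle1a.1 above the floor on 1, 3, 2 and 1 of its 4 arrays. Kitl, the ligand of the receptor KIT, and Zg16 were at the floor on all 4 Sle1a.1 arrays and at least 1.94-fold and 2.38-fold lower there.

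**Figure D2:**
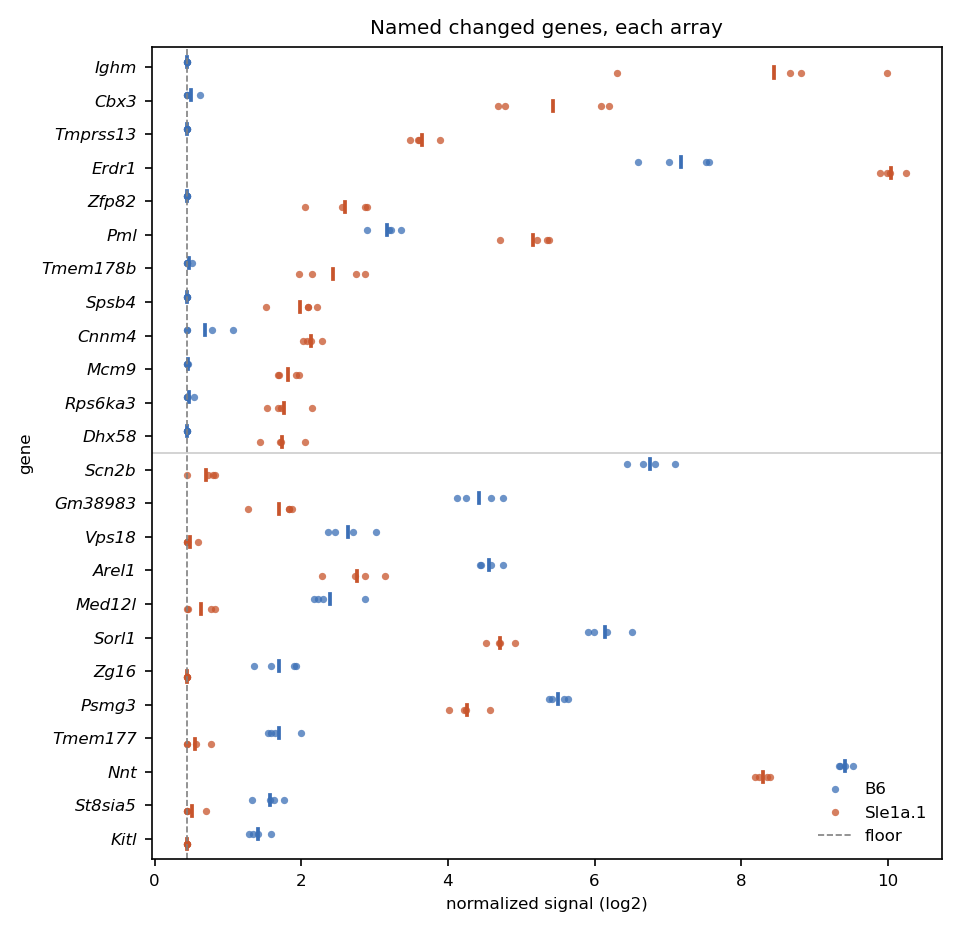
Normalized signal (log2, horizontal axis) of the 12 genes with the largest rise and the 12 with the largest fall among changed probe sets, 1 row per gene. Points are single arrays (blue for B6, orange for Sle1a.1), vertical marks are means of 4 arrays and the dashed line is the floor at 0.45. The points of both strains do not overlap for any of the 24 genes, which were chosen for their change. Chance alone separates 2.86% of probe sets, and 7.74% of those above the floor on all arrays were separated here.

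In all, 57 of 45037 probe sets passed an adjusted p of 0.05 (limma, Benjamini-Hochberg), 33 of them higher and 24 lower in Sle1a.1, and 4334 had an unadjusted p under 0.05. The 57 probe sets held 37 named genes, 22 higher and 15 lower, and 20 probe sets that the annotation used here does not list. Among these unlisted ones, the largest rise was from 2.93 ± 0.51 to 10.29 ± 0.10 and the largest fall from 7.15 ± 0.59 to the floor. One strain was at the floor on all of its arrays for 22 of the 57, and 21 were above the floor on all 8 arrays. Further probe sets of Nnt, Zg16 and Spsb4 had differences of -1.31, -1.75 and 1.89 (unadjusted p = 8.7e-04, 0.00324 and 0.0367 in limma's fit). Of other named genes with further probe sets above the floor on 4 or more arrays, none had one with an unadjusted p under 0.05 in the same direction: Ighm had 9 such probe sets, Mcm9 3, Sorl1, Rps6ka3, Med12l, Pml and Kitl 2 each, and Scn2b, Dhx58, Vps18, Arel1, Zfp82, Cnnm4, Psmg3 and Tmem177 1 each. The count of changed probe sets was 30 without B6 replicate 2, 36 without B6 replicate 4 and 32 without Sle1a.1 replicate 1, and the balance turned without any single B6 array, with 14 higher and 28 lower, 11 and 19, 13 and 27, and 13 and 23 without B6 replicates 1 to 4. The count was 182 with no floor and 6 with a floor at a log10 value of 1. Tmprss13, Mcm9, Scn2b, Gm38983, Vps18, Nnt and Kitl passed with each of the 8 arrays left out in turn. The other 17 of the 24 genes named above did not in at least 1 of these fits. Mcm9, Vps18 and Kitl lay near the floor, and their differences were 0 at a raised floor. Kitl was at 1.41 ± 0.13 in B6, and its 2 further probe sets had differences of 0.75 and 0.24.

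Gene lists fixed before the data were examined were then compared as groups. With camera and a preset correlation of 0.01 between genes, 10 of 35 lists passed an adjusted p of 0.05, and 0 did with a correlation estimated from the arrays (1 of 35 at an unadjusted p under 0.05). No member of any list passed over all genes in the fit of 1 probe set per gene, in which 11 of 18193 genes passed and 2105 had an unadjusted p under 0.05. Without B6 replicate 3, 4 lists passed, and without Sle1a.1 replicate 2, 5 did.

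The T cell receptor signalling, regulatory, effector and memory, and follicular helper T cell lists passed upwards in Sle1a.1 at the preset correlation. The 26 measured members of the T cell receptor signalling list had a median difference of 0.15 (adjusted p = 0.00960, and adjusted p = 0.609 with an estimated correlation). B6 replicates 1 and 2, whose 5' signal was low, had list means of 8.07 and 8.09, against 8.29 and 8.27 in the other B6 arrays and 8.23 to 8.48 in Sle1a.1, and without both the median was 0.09 (adjusted p = 0.0121). None of its members passed when adjusted over the list alone, and Malt1 and Bcl10, adaptors of antigen receptor signalling to NF-kappa B, had the differences 0.73 and 0.90. The 23 regulatory T cell genes had a median of 0.25 (adjusted p = 0.00965, and adjusted p = 0.609 with an estimated correlation), with 0 adjusted over the list alone. At an unadjusted p under 0.05, 3 members were higher and 0 lower. Foxp3, Ikzf4 and Entpd1, not among those 3, had differences of -0.21, -0.36 and -0.28. Il2ra, the alpha chain of the interleukin-2 receptor, was at 6.15 ± 0.07 against 5.52 ± 0.41, Tnfrsf1b at 6.49 ± 0.45 against 4.98 ± 0.93, and the transcription factor Ikzf2 at 8.26 ± 0.64 against 7.11 ± 0.75. B6 replicates 1 and 2, whose 5' signal was low, held the lowest B6 values of these 3 genes (Il2ra 5.17 and 5.18 against 5.91 and 5.85, Tnfrsf1b 4.63 and 3.87 against 5.97 and 5.45, Ikzf2 6.47 and 6.47 against 7.82 and 7.69). Without both arrays the list's median was 0.28 (adjusted p = 4.7e-04). With all 8 arrays, lists of erythroid, B cell and stromal markers were lower beside the higher T cell lists, and without both arrays the erythroid list still passed, with a median of -0.78 (adjusted p = 2.4e-04 at the preset correlation). With all arrays, it did not pass with an estimated correlation (adjusted p = 0.609). Among 22 effector and memory T cell genes the median was 0.21 (adjusted p = 0.00965, and adjusted p = 0.609 with an estimated correlation), and Ahnak and Crip1 rose when adjusted over the list alone (by 0.21 and 1.08, both adjusted p = 0.0390). Crip1 is also a close neighbour of Ighm on chromosome 12. The list's mean overlapped between the strains. It was 7.19 in B6 replicate 1, and 7.10, 7.45, 7.13 and 6.99 in Sle1a.1 replicates 1 to 4. In the other B6 arrays it was 6.83 to 6.86. The 15 follicular helper T cell genes had a median of 0.20 (adjusted p = 0.0355, and adjusted p = 0.704 with an estimated correlation). The list's mean stood apart in Sle1a.1 replicates 2 and 3 (7.78 and 7.67). In Sle1a.1 replicates 1 and 4 (6.87 and 6.79) it lay within the B6 range of 6.71 to 7.22. Of this list, Tox and Slamf6 had the differences 0.62 and 0.37, and 0 members passed adjusted over the list alone. At an unadjusted p under 0.05, 2 members were higher and 0 lower. Bcl6, Cxcr5 and Icos had differences of -0.09, 0.01 and -0.27. Without Sle1a.1 replicate 2, the regulatory, effector and memory, and follicular helper lists no longer passed (adjusted p = 0.145, 0.111 and 0.360). The effector and memory and the follicular helper lists also no longer passed without B6 replicate 3 (adjusted p = 0.0713 and 0.275), nor the latter without Sle1a.1 replicate 3 (adjusted p = 0.130). Under median scaling the effector and memory, follicular helper and regulatory medians were 0.04, 0.04 and 0.07, which is 0.21, 0.22 and 0.24 above the median of all probe sets, and the first pair did not pass (adjusted p = 0.157 for both, and 0.0432 for the regulatory list).

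The type I interferon response list, of 32 measured genes, had a median of 0.12 (adjusted p = 0.00965, and adjusted p = 0.609 with an estimated correlation). Usp18, a protease that removes ISG15, was at 5.77 ± 0.20 against 4.93 ± 0.34, Ifit1 at 6.27 ± 0.34 against 5.42 ± 0.27, and Ifi27l2a at 9.41 ± 0.18 against 8.96 ± 0.19. Of its members, 6 were higher and 0 lower at an unadjusted p under 0.05, 0 passed adjusted over the list alone, and the list did not pass without B6 replicate 3 (adjusted p = 0.0868). The 26 ribosomal protein genes had a median of 0.07 (adjusted p = 0.0398, and adjusted p = 0.704 with an estimated correlation) and 0 members adjusted over the list alone, with Rpl22 at 10.76 ± 0.03 against 10.68 ± 0.06. Under median scaling, which moved the median of all probe sets above the floor from -0.02 to -0.17, the ribosomal list was at -0.10 and no longer passed (adjusted p = 0.502). Relative to the median of all probe sets it was at 0.07 there and at 0.08 before. It also did not pass without B6 replicate 1 or 2 or without Sle1a.1 replicate 1, 2 or 4 (adjusted p = 0.202, 0.127, 0.0634, 0.203 and 0.142). The T cell receptor and interferon lists turned to -0.02 and -0.03 under that scaling, which is 0.15 and 0.14 above the median of all probe sets, and did not pass (adjusted p = 0.275 and 0.257).

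The cell cycle list fell in Sle1a.1, with a median of -0.33 over 33 genes (adjusted p = 4.5e-05, and adjusted p = 0.609 with an estimated correlation). At an unadjusted p under 0.05, 15 members were lower and 0 higher, and 3 fell when adjusted over the list alone. These were Birc5, the inhibitor of apoptosis survivin, which acts in chromosome segregation and fell by 0.53, the replication licensing factor Cdc6 at 4.40 ± 0.20 against 5.13 ± 0.28, and cyclin A2 (Ccna2) at 8.24 ± 0.11 against 8.64 ± 0.15. Cdc20, an activator of the anaphase-promoting complex, had a difference of -0.74 and did not pass. Among the 8 fits that left out 1 array, the list passed in each, as did the T cell receptor list.

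Lists of erythroid, B cell and stromal markers were also lower in Sle1a.1. The 10 measured erythroid markers had a median of -0.59 (adjusted p = 0.0117, and adjusted p = 0.609 with an estimated correlation). Klf1 and Gata1, transcription factors of red cell development, fell by 0.95 and 0.78 when adjusted over the list alone, whereas the globin gene Hbb-b2 had a difference of -0.40 and Hba-a2 one of 0.55. This list did not pass without B6 replicate 3, B6 replicate 4 or Sle1a.1 replicate 1 (adjusted p = 0.105, 0.0573 and 0.0744). The 23 B cell markers had a median of -0.47 (adjusted p = 0.0341, and adjusted p = 0.765 with an estimated correlation), with 0 members adjusted over the list alone and Cd22 at 4.25 ± 0.45 against 5.44 ± 0.56. The 14 stromal and endothelial markers had a median of -0.41 (adjusted p = 0.0355, and adjusted p = 0.609 with an estimated correlation). The endothelial genes Cdh5 and Pecam1 fell by 0.96 and 0.98 when adjusted over that list alone. Without B6 replicates 1 and 2, whose 5' signal was low, the medians of the B cell and the stromal lists were -0.08 and -0.07 and neither passed (adjusted p = 0.666 and 0.660). The B cell list also did not pass without B6 replicate 1, B6 replicate 3, Sle1a.1 replicate 2 or Sle1a.1 replicate 3 (adjusted p = 0.524, 0.0713, 0.0842 and 0.108), and the stromal list not without any single B6 array or Sle1a.1 replicate 1 or 2 (adjusted p = 0.402, 0.306, 0.275, 0.130, 0.124 and 0.111).

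**Figure D3:**
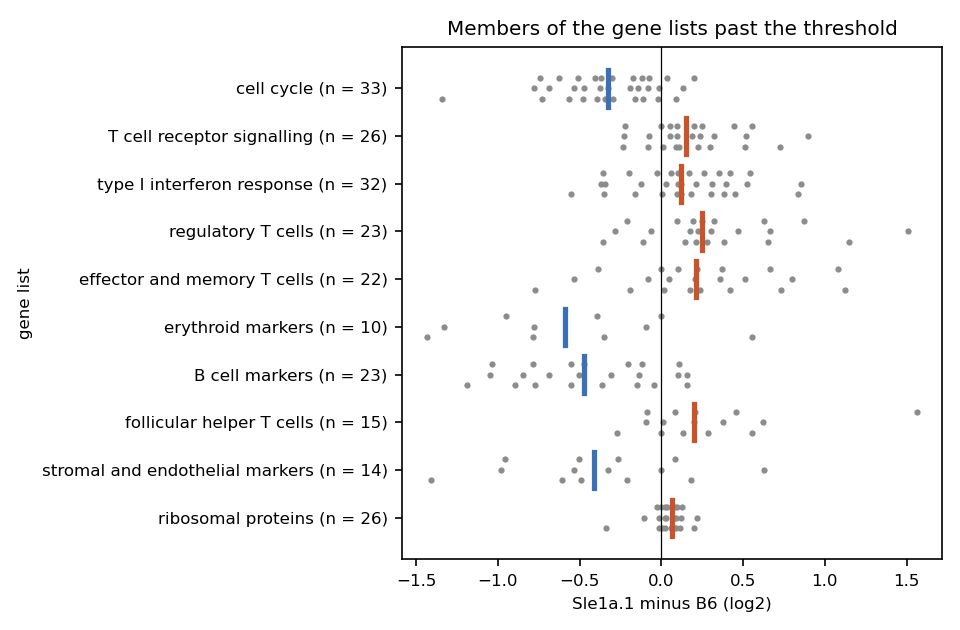
Difference between strains (Sle1a.1 minus B6, log2, horizontal axis) of each measured member (grey points) of the 10 gene lists that passed with camera at a preset correlation. Coloured bars are list medians (orange, higher; blue, lower in Sle1a.1), from -0.59 for erythroid markers to 0.25 for regulatory T cells; the position of points within a row has no meaning.

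Pbx1 itself was not analysed here, because the probe annotation used gives it no probe set. Its neighbours on chromosome 1 were compared instead, since a congenic segment can hold alleles of the donor strain. Of the 50 nearest measured protein-coding genes, 25 on each side, 7 had an unadjusted p under 0.05 (14.0%), against 2098 of 18143 other genes (11.6%), an odds ratio of 1.24 with a 95% interval from 0.47 to 2.80 (Fisher's exact test, two-sided p = 0.511). In limma's fit none of the 50 passed after adjustment. Among those 7, 6 were lower in Sle1a.1 and Cd247, the zeta chain of the T cell receptor complex, had a difference of 0.44. Nuf2, a kinetochore protein, and Uap1, an enzyme of UDP-N-acetylglucosamine synthesis, had differences of -0.56 and -0.32. The count of neighbours stayed on the same side of the threshold with 10 or 100 genes on each side (Fisher's exact p = 1 and 0.267).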

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

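In each strain the highest or lowest of 4 arrays was compared with the other 3 by Dixon's test for the 24 named genes, 6 array measures and 10 list means. Of 73 sets of 4 values tested, 11 passed, and chance gives about 1 in 20. Of these, 6 passed because 3 arrays had been raised to the same floor value, so the number that passed is not set against chance.

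For these 6 genes a single array lay above the floor of 0.45, which any value above it would have done. These were Cbx3 with 0.61 and Tmem178b with 0.51 in B6 replicate 4, Mcm9 with 0.46 in B6 replicate 2, Rps6ka3 with 0.54 in B6 replicate 3, Vps18 with 0.60 in Sle1a.1 replicate 4 and St8sia5 with 0.71 in Sle1a.1 replicate 2. Gm38983 was at 1.28 in Sle1a.1 replicate 4 and between 1.83 and 1.87 in the other 3. Med12l was at 2.87 in B6 replicate 3 and between 2.18 and 2.29 in the other 3.

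Sle1a.1 replicate 3 had a median deposited log10 value of 0.69, against 0.53 to 0.55 in the other Sle1a.1 arrays. Its mean correlation with the other 7 arrays was 0.948, against 0.972 to 0.973. The mean of the effector and memory T cell list was 7.19 in B6 replicate 1 and between 6.83 and 6.86 in the other B6 arrays.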

How the results depend on the processing

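The 57 changed probe sets (33 higher, 24 lower) depended on the treatment of dim signals, on single arrays of both strains and on a block by replicate number. Settings chosen after seeing the data gave 182 without a floor (110 higher, 72 lower; 21 shared with the 57), 170 without floor or normalization (82 and 88), 12 with a floor at a log10 value of 0.5 (6 and 6), 6 with a floor at 1 (1 and 5), 26 with log2(signal + 16) (15 and 11), 116 without B6 replicates 1 and 2 (13 and 103; 19 shared) and 26 with the Gapdh end ratio as a covariate (11 and 15). Of the planned ones, leaving out dim probe sets gave 33 (17 higher), the deposited values with the floor gave 15 lower, and an adjusted p under 0.10 gave 92. With 1 array left out, the count lay between 30 and 70, with 11 to 49 higher and 10 to 28 lower, and more lower than higher without any single B6 array. The cause of these moves was not tested. The 24 named genes did not turn direction under any alternative, with both strains at a raised floor in 14 cases, but of 515 gene and setting pairs 272 no longer passed. The arrays of both strains did not overlap for any of these genes. Leaving out arrays, array weights, a block or another variance model could therefore not turn their direction, so these settings do not test it.

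The 10 lists became 5 under median scaling, 5 with the mean of all probe sets of a gene, 6 without floor or normalization, 0 with an estimated correlation, and between 4 (without B6 replicate 3) and 10 with 1 array left out. The ribosomal list was at -0.10 under median scaling, which moved all probe sets, and relative to these it stayed higher (0.07, against 0.08). The cell cycle list passed in 24 of 25 alternatives, the exception being the estimated correlation. The genes next to Pbx1 stayed on the same side in all 26.

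Replicate numbers are shared by both strains, but no label says that they pair mice. Deviations of arrays with the same number correlated at 0.08, -0.02, 0.19 and 0.02, and 3 of 8 arrays correlated best with their own number, so the numbers were not taken as pairs. With the number as a block, limma called 0 probe sets (0 higher, 0 lower; 5092 at an unadjusted p under 0.05) and camera 6 lists. Pseudocounts planned for a linear table and the alternatives for Pbx1 were not run, since the table is on a log scale and Pbx1 was not analysed here. Changes near the floor, where 22 of the 57 have a strain wholly at it, are limited by signal over background.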

Other observations

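The tests on chromosome 9, the splits for the genes next to Pbx1, the test without B6 replicates 1 and 2 and that of the B cell markers were chosen only after the result was seen. On chromosome 9 the window of neighbouring genes was tested first and did not pass, and the count over the whole chromosome was made after that.

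The retinoic acid list (26 genes, adjusted p = 0.810) and the PBX and TALE partners (19 genes, adjusted p = 0.810) did not pass. In the former, Ncoa3, a nuclear receptor coactivator, rose by 0.21 when adjusted over the list alone (adjusted p = 0.0477), and Dhrs3 and Aldh1a1 had differences of 1.56 and -0.64 without passing. Among PBX partners, Hoxb7 was at 3.01 ± 0.96 against 1.08 ± 0.29 and Hoxa9 at 1.92 ± 0.42 against 2.69 ± 0.49, neither past the threshold. The Ifi200 genes of chromosome 1 had a median of 0.38 and an adjusted p of 0.131. The Slam family list (adjusted p = 0.536) held Cd48 at 7.83 ± 0.19 against 6.65 ± 0.84, and the list of chromosome 1 genes near Pbx1 had an adjusted p of 0.536.

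The Th1, Th2 and Th17 lists did not pass (camera, adjusted p = 0.426, 0.782 and 0.392). In the latter, Il17a was at 2.42 ± 0.56 in Sle1a.1 and 0.79 ± 0.68 in B6, above the floor on 4 and 1 arrays, and did not pass adjusted over the list alone. T cell activation had a median of 0.12 (adjusted p = 0.0682), with Nfatc1 at 8.53 ± 0.33 against 7.63 ± 0.39, and naive and central memory genes had an adjusted p of 0.939. Single members passed when adjusted over their list alone. Sc5d of cholesterol synthesis rose by 1.18, the glycolytic enzyme Pkm by 0.86, the chaperone Dnaja1 by 0.53 and Skil and Smurf1 of TGF-beta signalling by 0.25 and 0.36, while the apoptosis inhibitor Birc2 fell by 0.48. Their lists did not pass, with adjusted p of 0.782 for cholesterol synthesis, 0.533 for glycolysis, 0.208 for stress and immediate early genes, 0.280 for TGF-beta signalling and 0.690 for apoptosis. Sc5d, Pkm and Birc2 lie on chromosome 9, among its genes at an unadjusted p under 0.001 that are described below. A second probe set of Sc5d had a difference of 0.16 (unadjusted p = 0.678 in limma's fit). Oxidative phosphorylation (adjusted p = 0.0825), the unfolded protein response (0.967) and chemokine receptors (0.797) did not pass. Neither did dendritic cell (0.180), B-1a and plasma cell (0.188), neutrophil (0.426), NK cell (0.533), CD8 T cell (0.536), platelet (0.538) and monocyte markers (0.700). The median and the test's direction differed in sign for the Slam, PBX and naive lists, as did the mean and the test for Th1 and chemokine receptors.

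Each of the 35 splits of the 8 arrays into 4 and 4 was fitted in the same way. Only 1 split, the real one, gave as many changed probe sets (57, highest other 4). With 35 splits, a share of 1 of 35 is the smallest that can be reached. The other splits mix both strains within a group, so a strain difference adds to their spread and can lower their counts. Chance is therefore argued against but not excluded for this count, and with replicate numbers as a block 0 probe sets were called. At an unadjusted p under 0.05, however, the split of B6 replicates 1, 2 and 4 with Sle1a.1 replicate 1 against the other arrays gave 5396 probe sets, more than the 4334 of the real one, so an excess at that level also arose from structure of the samples other than strain. For the gene lists chance cannot be excluded: 4 of the 35 splits gave 10 or more, and the highest of the others gave 14. Among genes next to Pbx1, the real split gave 7 at an unadjusted p under 0.05, but this number follows how many genes pass in a split. Relative to other genes, 12 of the 35 splits gave an odds ratio as high as the real 1.24 (highest other 6.49), so chance cannot be excluded.

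Changed genes were frequent on chromosome 9. Of 98 genes at an unadjusted p under 0.001, 18 lay there (1.79% of its 1006 genes, odds ratio 3.88; Fisher's exact test, adjusted p = 1.3e-04 over the 20 chromosomes), as did 9 of the 37 called genes, among them Scn2b, Tmprss13, Pml, Sorl1 and Spsb4, which argues against random placement. Of these, Pml and Sorl1 each had a brighter probe set with a difference of the opposite sign. Only 1 of the 35 splits, the real one, gave a chromosome as small a p (-log10 of the one-sided p 5.19, highest other 2.48), but the other splits held 60 or fewer such genes and reached smaller p less easily, so a chance division of the arrays is not excluded by this, and 5 of 22 alternatives had a Fisher's exact p of 0.05 or more (0.0814 without Sle1a.1 replicate 2, 0.186 without B6 replicates 1 and 2, 0.193 with replicate numbers as a block, 0.0686 without floor or normalization and 0.152 with the Gapdh covariate). A stretch of donor sequence on chromosome 9 may differ between the strains, but its tests decided nothing: a window as full as the fullest of 50 neighbouring genes, of which there were 2 with 4 genes each, was reached in a share of 0.187 of shuffles, the places were as close together in a share of 0.167 of random draws, and remaining genes of a stretch of 114 genes around 1 of these windows were not shown to be more often at p under 0.05 (Fisher's exact p = 0.872, odds ratio 0.89, 95% interval 0.41 to 1.73). Donor variants under single probe sets also stay open. Of 11 other probe sets of 7 of the 18 genes, 63.6% had the same direction (exact 95% interval 30.8% to 89.1%). At an unadjusted p under 0.05 in limma's fit, 0 had the same direction and 2 the opposite one. The latter were in Siae (0.94 against -0.83, unadjusted p = 0.0104) and Arcn1 (0.79 against -0.39, unadjusted p = 0.00307).

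The cell cycle list was lower in Sle1a.1, with a median of -0.33. Chance cannot be excluded, since 2 of the 35 splits gave a shift as large (highest other 0.39). B6 replicates 1 and 2, with their low 5' signal, did not alone make the shift. Without them the median was -0.37 (camera, adjusted p = 2.2e-09 at the preset correlation, while with all arrays the adjusted p was 0.609 with an estimated correlation). That preset p carries little weight, since a split that mixed the strains reached 1.2e-15. RNA ends stay open as a cause, because Actb ends of B6 replicates 3 and 4 (-2.03 and -1.79) still lay below all Sle1a.1 arrays (-1.76 or higher). Fewer erythroid precursors among the Sle1a.1 cells may contribute: over the 8 arrays, deviations from the strain means correlated between the erythroid and the cell cycle lists (Pearson r = 0.85, permutation p = 0.0278; Spearman rho = 0.67, permutation p = 0.0903; r = 0.76 without the 2 farthest arrays; 1 relation tested), although Hba-a2, with a difference of 0.55, and Car2, at 9.50 ± 0.25 against 9.51 ± 0.48, did not follow Klf1 and Gata1. The correlation was not run with other lists, so it does not tell erythroid precursors from a factor that moved many lists on the same arrays. Oxidative phosphorylation, for example, also had its lowest B6 mean in replicate 2 (7.79). Its highest Sle1a.1 mean was in replicate 2 too (7.86), as for the cell cycle list (5.91 and 6.07). A difference of the T cells between the strains was not tested and stays open.

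The Ighm probe set that was at the floor in B6 may point to B cells or plasma cells among the Sle1a.1 cells, or to a difference at the heavy chain locus. More B cells are argued against, because the other 20 B cell markers above the floor had a median of -0.49, 17 of them lower, and although the B cell list was at -0.17 without B6 replicate 1 and at -0.08 without B6 replicates 1 and 2 (camera, adjusted p = 0.524 and 0.666), it was not higher in either fit. The 9 other Ighm probe sets above the floor on 4 or more arrays had differences between 0.10 and 0.92. None had an unadjusted p under 0.05 in limma's fit. The brightest of them were at 8.18 ± 0.11 and 7.17 ± 0.52 in B6, so Ighm signal was present in that strain too. A strain difference around the locus on chromosome 12 stays open, with 6 of 45 neighbouring genes at an unadjusted p under 0.05 (13.3% against 11.6%; Fisher's exact p = 0.642). Of these 6, Zfp386 and Crip1 had differences of 1.87 and 1.08 (unadjusted p = 1.3e-04 and 0.00354, adjusted p = 0.0871 and 0.250 in limma's fit). Brf1, Pld4, Siva1 and Pacs2 had differences between -0.96 and -0.84.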
